A study of Drosophila melanogaster with 9 samples.

How the data were processed

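Gene expression was measured in whole guts of adult Oregon R females by stranded mRNA sequencing, from total RNA taken with Trizol and made into libraries with a TruSeq Stranded mRNA kit, per the labels. Per the submitters' processing notes the reads were handled with CASAVA 1.82 and Bowtie2 2.1, and limma was used. The genome build, the annotation and whether counting used the strand are not given in the sources used here.

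The deposited values were log2 RPKM, although the fixed design had taken them to be RPKM. They had the form log2((reads + 0.5) / (library total + 1) / length) per transcript, scaled to RPKM and averaged on the log scale over the transcripts of a gene. The added 0.5 and 1 are those that limma's voom uses. RPKM was therefore taken as 2 to the power of the deposited value, and comparisons were made on log2(RPKM + 1). The form was checked by solving for the library totals with transcript lengths of the BDGP6.54 assembly. Within a relative tolerance of 3e-12 whole read numbers were found for 6808 genes (66.5%), among them 3181 of 3317 genes with 1 transcript (95.9%), and for 519 of the 766 genes with 2 transcripts. Gene names were matched to current symbols (7878 current, 2314 older and 53 with none), and 98.4% of genes had a length. Library totals per sample are given with the results. The 9 values of 190 genes equal those of another gene, 103 of them histone genes, so reads of overlapping or near-identical genes were shared.

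The 9 libraries were grouped by diet, 3 per diet, and compared as glucose versus agar, glucose versus standard and agar versus standard. Groups, comparisons, alternatives and 36 gene lists were fixed before the data were examined. Genes with at least 1 RPKM in at least 3 libraries were tested (8036). One limma fit with a group mean per diet, empirical Bayes moderation and a variance trend was used (residual df 6, prior df 2.752), and an adjusted p is the Benjamini-Hochberg value over all tested genes, called when under 0.05. "Adjusted over the list alone" applies the same correction within a list. Of the lists 33 had at least 3 tested members and went through camera with a preset correlation of 0.01, its p adjusted over the 33. Calls with an estimated correlation are given beside each, and fry was run for movement to one side on balance and in either direction. Camera sets a list against all other genes, and fry does not. Matching of list names was tightened after list results had first been seen, to follow the fixed rule that a name match the gene itself; this changed the membership of the cytosolic ribosomal proteins.

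Genes are named by a fixed rule. Per comparison these are the 8 largest rises and 8 largest falls past the threshold with a mean of at least 10 RPKM in the higher group and no overlap, the 2 members with the smallest p in each list with called members, and daw, babo, Smox, put, tobi, Amy-p, Amy-d, Mal-A1, Mal-B1, sug, mag and Thor. Marker genes named with other cell types are the members with the highest level.

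Alternatives were pseudocounts of 0.1 and 5, no filter and a stricter filter of 5 RPKM, median-ratio scaling (each library divided by its median ratio to the geometric mean of the libraries), quantile normalization, a fit of the 6 compared libraries alone, the repeat number as a block, no variance trend, library weights and each library left out in turn. The block was run because correlations of residuals between libraries of the same repeat number were 0.1723 to 0.5905 and those between others -0.5289 to 0.2872. A fit of the deposited log2 values, median-ratio scaling with the block, and standard replicate 1 as the only standard library were added after the data had been seen.

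The procedure was tested on simulated data with 200 of 8036 genes changed, drawn from genes of higher mean level. The trypsins and Jonah serine proteases were also lowered as a list. Noise was drawn independently per gene and library, without the likeness of libraries of the same repeat number, so recovery in the data may differ. Genes changed 2-fold were called in 76%, 74% and 80% of cases in the 3 comparisons as listed above, genes changed 4-fold in 97%, 93% and 96%, and 12, 11 and 3 unchanged genes were called. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9. Raw reads were not used here.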

Results

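RNA was sequenced from whole guts of adult female Drosophila melanogaster of the Oregon R strain fed standard medium, 10% glucose or agar, with 3 biological repeats per diet and 9 libraries in all. Each library was given as 1 log2 RPKM value per gene, where RPKM is the number of reads per kilobase of transcript relative to the library total. The 8036 genes with at least 1 RPKM in at least 3 libraries were compared. Library totals recovered from the values were 37947126, 34899709 and 43477728 reads on agar, 37886312, 39606248 and 37036132 on glucose, and 48389188, 43851820 and 44271311 on standard medium, for repeats 1, 2 and 3 in each case. At these totals 1 read per kilobase stood for 0.0207 to 0.0287 RPKM. Values below are mean RPKM ± SD with n = 3 per diet, and differences are on the log2(RPKM + 1) scale.

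Libraries of 1 diet were not equally alike. Pearson's r across genes, which are not independent replicates, was 0.984 to 0.992 among glucose libraries, 0.958 to 0.984 among agar libraries and 0.953 to 0.986 among standard libraries. On the first principal component (52.2% of the variance) standard replicates 2 and 3 lay at 42.5 and 40.0 and standard replicate 1 at 7.16. The other 6 libraries lay between -20.1 and -10.4. Agar replicate 3 lay at -33.9 on the second component (24.1%) and standard replicate 1 at 26.0. The 110 replication-dependent histone genes were a median of 3.98 and 3.32 above their median library in standard replicates 2 and 3, and 6 ribosomal RNA genes and pseudogenes were 3.97 and 3.36 above it. Standard replicate 1 gave -0.19 and -0.33 for the same classes. Cytosolic ribosomal protein genes lay at -0.82 in agar replicate 3 and at -0.50 and -0.53 in standard replicates 2 and 3.

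**Figure D1:**
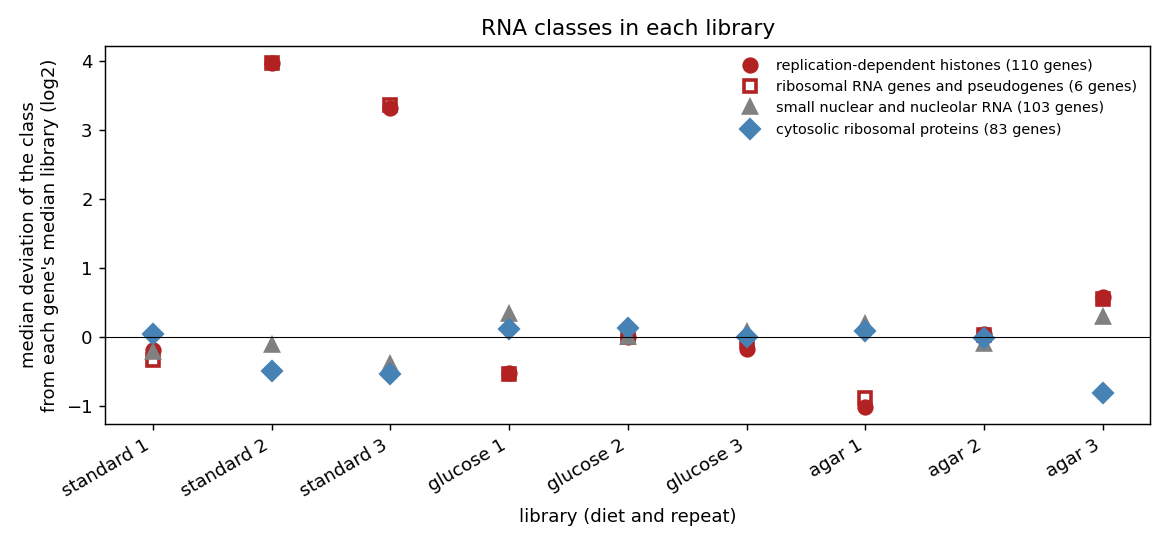
Median deviation of 4 classes of RNA from each gene's median library (vertical axis, log2) in each of the 9 libraries (horizontal axis), 1 point per class and library. The medians of histone and ribosomal RNA genes stood at 3.32 to 3.98 in standard replicates 2 and 3, and cytosolic ribosomal protein genes at -0.82 in agar replicate 3.

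Genes listed as markers of muscle and fat body were detected in all 9 libraries, and from which tissue their transcripts came was not tested. The muscle marker Act57B ranged from 75.7 to 142.5 RPKM over the 9 libraries and the fat body marker to from 66.2 to 150.5. The neuronal gene Syx1A ranged from 3.68 to 7.27, the Malpighian tubule gene TyrR from 1.52 to 3.37 and the haemocyte gene Sr-CI from 0.0385 to 0.162. The ovary gene osk reached 2.14 in glucose replicate 2 and at most 0.0966 in any other library. For muscle markers (other cell type), 15 tested, the median difference was -0.02 for glucose versus agar, 0.11 for glucose versus standard and 0.02 for agar versus standard, with camera directions of up, down and down and adjusted p of 0.811, 0.0619 and 0.0803. After median-ratio scaling these medians were 0.02, -0.20 and -0.34, and after quantile normalization 0.07, 0.10 and -0.04. The first comparison passed without glucose replicate 3 (0.0453), the second without glucose replicate 1 (0.0299), glucose replicate 2 (0.00566) or standard replicate 3 (0.00593), and the third without agar replicate 2 (0.0368) or standard replicate 3 (0.00903). Tm1 and Mf were the 2 muscle markers called over all genes (0 adjusted over the list alone), both higher on agar than on standard medium (0.40 and 0.58, adjusted p = 0.0259 and 0.0457) and neither after scaling (0.04 and 0.22 after median-ratio scaling). For fat body markers (other cell type), 5 tested, the medians were 0.16, -0.01 and -0.18, with camera adjusted p of 0.122, 0.0927 and 0.0106 (adjusted p = 0.146 with an estimated correlation, and 0.128 after median-ratio scaling, for the last). The mean of the second was 0.04. Without agar replicate 1 the first of these was 0.0331. The yolk protein gene Yp2 was the 1 member called by either count, at 37.6 ± 19.6 on agar and 83.2 ± 14.1 on standard medium (-1.24, adjusted p = 0.0196, 0.0781 after quantile normalization, and 0.0512 without standard replicate 1). For Malpighian tubule markers (other cell type), 3 tested, the medians were 0.01, 0.30 and 0.08 (camera up, down and down, adjusted p = 0.739, 0.456 and 0.287), the first being -0.01 after quantile normalization and the last -0.17 after either scaling. Of the neuron markers 1 was above the filter (0.19, 0.19 and 0.00), and of the ovary and haemocyte markers 0 were.

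Glucose was compared with agar to see what sugar does to a gut that is otherwise given no nutrient, the question the series title raises for digestive enzymes. Several enzymes that break down carbohydrate and fat were lower on glucose. Gal, a beta-galactosidase gene, fell from 56.5 ± 7.21 RPKM on agar to 15.9 ± 1.75 on glucose (-1.76, SE 0.13, adjusted p = 0.00270). Amyrel, which is related to the amylases, fell from 49.2 ± 24.9 to 6.01 ± 1.00 (-2.69, SE 0.36, adjusted p = 0.0412). The lipase gene CG8093 fell from 303 ± 137 to 44.9 ± 15.2 (-2.68, adjusted p = 0.0412). The lipase genes CG6277, CG6271 and CG6283 fell (-2.29, -2.28 and -1.28, adjusted p = 0.0478, 0.0412 and 0.0403), as did CG31148, the acyl-CoA dehydrogenase gene CG3902 and CG7916 (-2.03, -1.61 and -1.34, adjusted p = 0.0290, 0.0412 and 0.0454). Among genes meeting the rule for large rises, CG3348 was at 121 ± 16.4 on glucose and 32.0 ± 8.91 on agar (1.92, adjusted p = 0.0444). CG10182 was at 51.6 ± 6.75 and 26.0 ± 1.89 (0.96, adjusted p = 0.0444).

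All 13 tested genes of the amylases and maltases had negative differences, from -0.24 to -3.18 with a median of -1.39. Over all genes 1 was called lower and 0 higher, and 9 were lower when adjusted over the list alone. With the repeat number as a block 9 were called over all genes. The list lay below other genes by camera (adjusted p = 4.53e-13, and adjusted p = 0.268 with an estimated correlation). The maltase-like gene tobi was at 83.6 ± 3.75 on glucose and 773 ± 395 on agar (-3.02, adjusted p = 0.0562, 0.0316 with the block, and 0.0117 to 0.237 over the alternatives). Mal-A1 was at 223 ± 56.7 and 1208 ± 551 (-2.33, adjusted p = 0.0682, 0.0170 with the block, and 0.0130 to 0.282 over the alternatives). Without agar replicate 1 both passed, at 0.0117 and 0.0130. The list median was 6.44 log2 units in agar replicate 1 and 8.32 and 7.86 in agar replicates 2 and 3. The amylase genes proper, which are near-identical and may share reads, were at 785 ± 170 on glucose and 1075 ± 593 on agar for Amy-p (-0.26, adjusted p = 0.953, and 0.08 and 0.02 without agar replicates 1 and 2). Amy-d was at 515 ± 56.7 and 759 ± 287 (-0.48, adjusted p = 0.735). Mal-B1 was below the filter, at 0.441 ± 0.130 and 0.644 ± 0.328.

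**Figure D2:**
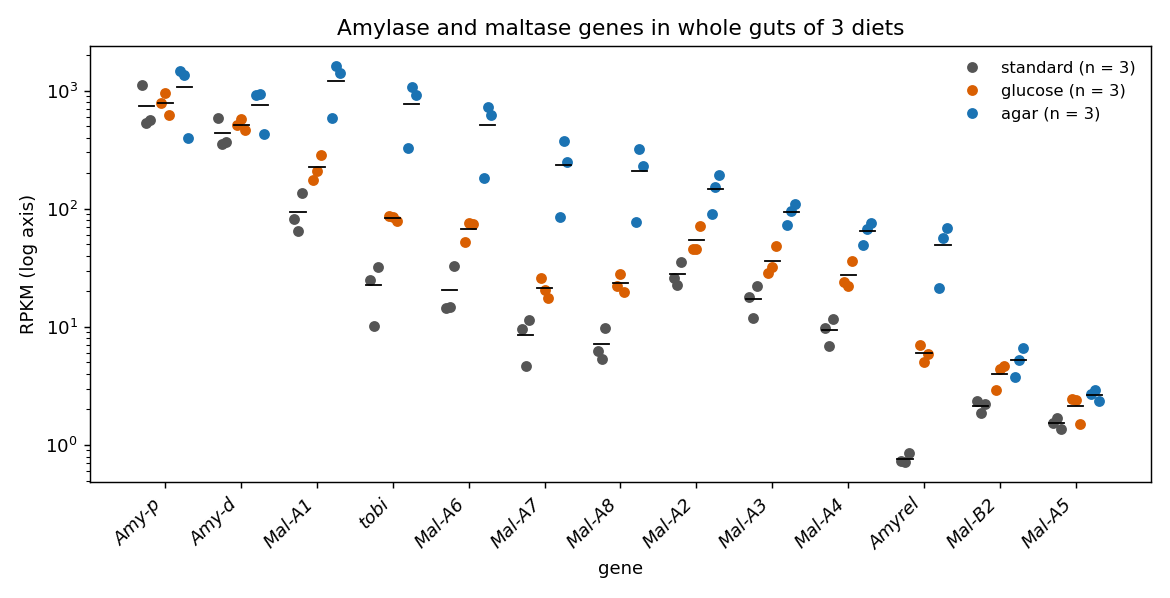
RPKM (vertical axis, log scale) of the 13 tested genes of the amylases and maltases (horizontal axis) in each library, with 3 points per diet and a black bar at their mean. Mal-A1, for example, had means of 94.3 on standard medium, 223 on glucose and 1208 on agar, whereas Amy-p had 733, 785 and 1075.

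The remaining enzyme lists went different ways. Of 9 tested other glycosidases, 1 was lower over all genes (5 with the block) and 6 were lower adjusted over the list alone. The median of the other glycosidases was -1.28 (camera adjusted p = 3.16e-07, and adjusted p = 0.269 with an estimated correlation). Of 16 lipases, 4 were lower (7 with the block, 3 after median-ratio scaling and 0 after quantile normalization, where the median was -0.12). Adjusted over the list alone 2 were higher and 6 lower. The lipases had a median of -0.15 and a mean of -0.69 (camera adjusted p = 0.00838, 0.0700 without agar replicate 1, and adjusted p = 0.268 with an estimated correlation). The lipase gene mag was at 485 ± 62.0 on glucose and 490 ± 155 on agar (0.02, adjusted p = 0.998), with a difference of -0.06 after quantile normalization, -0.01 with library weights and -0.12 and -0.08 without agar replicates 2 and 3, and -0.07 without glucose replicate 3. Over all genes and adjusted over the list alone, 0 of 33 trypsins and Jonah serine proteases (median 0.22, camera adjusted p = 0.144, and 0.00192 without agar replicate 1) and 0 of 22 other secreted peptidases (median 0.14) were called. By limma with the block, 1 of the trypsins and Jonah serine proteases was lower. The other secreted peptidases lay above other genes (camera adjusted p = 0.0108, 0.257 without agar replicate 2, 0.0695 without glucose replicate 3, and adjusted p = 0.411 with an estimated correlation). For the sterol and lipid absorption list, 0 of 14 were called (median -0.08, mean and camera direction positive, adjusted p = 0.917).

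Genes of sugar sensing were higher on glucose as a list, with 0 of 5 called over all genes and 3 adjusted over the list alone. The list median was 0.38 (camera adjusted p = 0.00365, and adjusted p = 0.282 with an estimated correlation). With the block 1 was called. This was sug, a transcription factor gene, at 58.6 ± 13.3 on glucose and 25.9 ± 13.4 on agar (1.24, adjusted p = 0.229, 0.0472 with the block, 0.0496 without agar replicate 1, and 0.0472 to 0.615 over the alternatives). Of 13 sugar transporters 0 were called over all genes (2 higher and 3 lower with the block), and 1 higher and 3 lower adjusted over the list alone. Their median was -0.21 (camera adjusted p = 0.0195, 0.125 without agar replicate 3, 0.0513 without glucose replicate 2, and adjusted p = 0.411 with an estimated correlation). Of 12 amino acid transporters 0 were called over all genes (1 higher and 1 lower with the block), and 3 higher and 1 lower adjusted over the list alone. Their median was 0.18 (camera up, adjusted p = 0.0108, 0.102 without agar replicate 1, and adjusted p = 0.269 with an estimated correlation). Of 13 genes of fatty acid oxidation 0 were called over all genes (1 lower with the block) and 2 lower adjusted over the list alone. Their median was -0.23 (camera down, adjusted p = 0.0108, 0.381 without agar replicate 1, and adjusted p = 0.411 with an estimated correlation). Glycolysis (13 genes, median 0.06, adjusted p = 0.779), lipogenesis and NADPH supply (11, 0.08, 0.260), starvation and FOXO targets (11, 0.08, 0.235) and autophagy (15, -0.07, 0.830) had 0 members called by limma without the block. The autophagy median was 0.00 after quantile normalization and its camera direction was up. Thor, the 4E-BP gene, was at 253 ± 50.2 on glucose and 201 ± 63.3 on agar (0.36, adjusted p = 0.780).

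The activin-like ligand gene daw was at 20.5 ± 6.92 RPKM on glucose and 12.3 ± 0.526 on agar, with all 3 glucose libraries above all 3 agar libraries, and did not pass (0.65, SE 0.21, adjusted p = 0.280, and 0.0845 to 0.597 over the alternatives). Its type I receptor gene babo was at 5.93 ± 0.502 and 7.02 ± 2.0971 (-0.18, adjusted p = 0.846, and 0.02 without agar replicate 3), and the Smad gene Smox at 7.35 ± 0.664 and 7.35 ± 1.64 (0.01, adjusted p = 0.998, with -0.08 and -0.05 without agar replicates 1 and 2 and -0.05 without glucose replicate 3). The type II receptor gene put was at 7.69 ± 0.585 and 7.30 ± 0.416 (0.07, adjusted p = 0.908). By limma 0 of 8 genes in the TGF-beta/activin pathway were called over all genes and adjusted over the list alone (median 0.02, camera adjusted p = 0.260), and 0 of 8 in the BMP pathway (median 0.03, adjusted p = 0.440).

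Detoxification genes had a median of -0.30, with 0 of 19 called over all genes (3 lower with the block) and 6 lower adjusted over the list alone (camera adjusted p = 3.53e-05, and adjusted p = 0.411 with an estimated correlation). Higher on glucose as lists, with 0 members called over all genes or adjusted over the list alone, were heat shock and Turandot genes (13, median 0.34, camera adjusted p = 3.49e-04, 0.0709 without glucose replicate 2, and adjusted p = 0.411 with an estimated correlation) and ribosome biogenesis genes (18, 0.25, 2.90e-06, and adjusted p = 0.411 with an estimated correlation, 3 members with the block). Of 83 genes for cytosolic ribosomal proteins 81 were above 0 and 0 were called either way (median 0.33, camera adjusted p = 1.13e-12, and adjusted p = 0.411 with an estimated correlation). Without agar replicate 3, in which these genes lay at -0.82, their median was 0.07 (adjusted p = 0.00251). The progenitor markers and mitogens had a median of 0.03 and a mean of 0.28, with 0 of 5 called over all genes (2 higher with the block) and 2 higher adjusted over the list alone (camera adjusted p = 0.0195, and adjusted p = 0.282 with an estimated correlation). In the other lists 0 members were called by limma. These were antimicrobial peptides (4, 0.35, adjusted p = 0.127, and 0.00403 without glucose replicate 1), peptidoglycan recognition and Imd regulators (11, 0.16, 0.144, and 0.0371 without glucose replicate 3) and lysozymes (6, 0.33, 0.0904, 0.0422 with the block, 0.00407 without agar replicate 1 and 0.0286 without glucose replicate 3). They were also mucins and peritrophic matrix (5, -0.21, 0.917), oxidative phosphorylation (23, 0.07, 0.211, 0.0443 after quantile normalization and 0.00616 without agar replicate 1), circadian clock (8, 0.12, 0.0525, 0.0422 with the block, 0.0415 after quantile normalization, 0.0380 without agar replicate 2, 0.0407 without agar replicate 3 and 0.0329 without glucose replicate 1) and cell division (3, 0.08, 0.811). Enteroendocrine peptides (11, -0.02, 0.739) and the vacuolar ATPase and copper cell list (14, -0.03, 0.917) completed them. Both of these had a camera direction of up, and the median of the first was 0.01 after median-ratio scaling and that of the second 0.01 after either scaling.

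By fry, which does not set a list against other genes, 0 of 33 lists moved up on balance and 3 down. In either direction 7 changed. In all, limma called 3 genes higher and 20 lower on glucose than on agar at a Benjamini-Hochberg adjusted p under 0.05, 1 of them at least doubled and 13 reduced to 0.5 times or less. The unadjusted p was under 0.05 for 845 genes. The groups did not overlap in 1249 genes (15.5%, against 10% by chance). With the block 51 were higher and 140 lower. After median-ratio scaling 3 were higher and 14 lower, and after quantile normalization 2 and 9. Without agar replicate 1 the counts were 22 and 93, without standard replicate 1 they were 2 and 7, and without any 1 of the other 7 libraries 0 or 1 were higher and 1 or 2 lower. Of the 11 named genes called, Gal alone kept its call without each library in turn (adjusted p up to 0.0332). The other 10 lost it without agar replicate 2, each glucose replicate or standard replicate 2 or 3, 9 without agar replicate 3 and 6 without standard replicate 1, with adjusted p of up to 0.201 (CG10182, without agar replicate 2). CG6277 and CG7916 also missed the threshold after median-ratio scaling (0.0569 and 0.0537). After quantile normalization 6 of the 11 lost the call (CG6271, CG8093, CG6277, CG3348, CG6283 and CG7916, at 0.0519 to 0.163). Without a filter 8 lost it, and with a fit of the 6 compared libraries 10.

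Glucose was next compared with standard medium, which sets sugar alone against a complete food. CG3290 rose from 1.46 ± 0.450 RPKM on standard medium to 32.3 ± 9.04 on glucose (3.74, SE 0.30, adjusted p = 0.00217). CG13215 rose from 2.09 ± 0.913 to 28.2 ± 5.07 (3.27, adjusted p = 0.00217). The acid sphingomyelinase-like gene CG15533 rose by 3.09 (adjusted p = 0.00965), and the like gene CG15534 also rose (adjusted p = 0.0134). The Jonah serine protease gene Jon25Bii fell from 1478 ± 269 to 218 ± 71.7 (-2.79, SE 0.34, adjusted p = 0.00965). Jon25Bi fell from 2445 ± 254 to 406 ± 163 (-2.67, adjusted p = 0.00965). This pair resembles one another in sequence, so reads may be shared. These 6 genes passed under each scaling. CG34203 rose by 1.90 (adjusted p = 0.00965) and CG7298 by 1.65 (adjusted p = 0.0338, and 0.165 after median-ratio scaling).

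Most genes lay higher on glucose than on standard medium, with a median difference of 0.25 over the 8036 genes that was -0.00 after median-ratio scaling and 0.02 after quantile normalization. Differences smaller than this shift therefore depend on the scaling. Of the amylases and maltases 7 of 13 were higher over all genes, 10 were higher adjusted over the list alone, and 0 were called after either scaling. The list median was 1.27, or 1.02 above the median gene, and 0.94 and 1.09 after the 2 scalings (camera adjusted p = 0.0606, and 2.87e-05 after median-ratio scaling, with 1.76e-05 to 0.676 over camera settings). Without agar replicate 1 the list passed at 0.00486, without agar replicate 2 at 0.0481, without glucose replicate 1 at 0.0428, without glucose replicate 3 at 0.0491 and without standard replicate 3 at 0.0198. Examples of the amylases and maltases called were tobi, from 22.4 ± 11.1 to 83.6 ± 3.75 (1.99, adjusted p = 0.0283, and 0.150 after median-ratio scaling), Amyrel, from 0.765 ± 0.0768 to 6.01 ± 1.00 (1.98, adjusted p = 0.0179, and 0.0612), Mal-A6 (1.74, adjusted p = 0.0439, and 0.203) and Mal-A4 (1.43, adjusted p = 0.0171, and 0.0820). Without glucose replicate 2 the adjusted p was 0.0851 for tobi, 0.0647 for Amyrel and Mal-A4 and 0.118 for Mal-A6. Mal-A1 was at 223 ± 56.7 and 94.3 ± 36.8 (1.27, adjusted p = 0.0551, 0.0190 with the block, and 0.0137 to 0.297 over the alternatives), and it passed without agar replicate 1 or agar replicate 3, the lower value being 0.0248. Amy-p was at 785 ± 170 and 733 ± 326 (0.16, adjusted p = 0.806), and at -0.17 after median-ratio scaling and -0.03 without standard replicate 2. Amy-d was at 515 ± 56.7 and 437 ± 134 (0.27, adjusted p = 0.517), and at -0.06 after median-ratio scaling. Mal-B1, below the filter, was at 0.441 ± 0.130 and 0.176 ± 0.0587.

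Of 33 trypsins and Jonah serine proteases 5 were lower over all genes (1 higher and 14 lower with the block, 3 lower after either scaling) and 4 lower adjusted over the list alone. Their median was -0.41 (-0.74 and -0.25 after the 2 scalings), below other genes by camera (adjusted p = 5.42e-23, and adjusted p = 0.293 with an estimated correlation). CG18179 of this list fell from 87.3 ± 8.83 to 26.8 ± 4.14 (-1.67, adjusted p = 0.00965). The other secreted peptidases had a median of 0.01, a mean of -0.03 and 1 of 22 called, CG15255, which was higher (0.52, adjusted p = 0.0242, and 0.511 after median-ratio scaling). With the block 3 were higher and 3 lower, and adjusted over the list alone 1 was higher. They lay below other genes (camera adjusted p = 7.31e-05, and adjusted p = 0.342 with an estimated correlation), with medians of -0.31 after median-ratio scaling and 0.04 after quantile normalization (adjusted p = 0.849). The other glycosidases had a median of -0.26 (camera adjusted p = 0.0101, 0.238 and 0.849 after the 2 scalings, 0.0624 without glucose replicate 1, 0.0588 without standard replicate 3, and adjusted p = 0.473 with an estimated correlation), with 1 of 9 higher over all genes (3 higher and 3 lower with the block) and 0 adjusted over the list alone. That member was Treh, the trehalase gene (0.71, adjusted p = 0.0459, and 0.408 after median-ratio scaling). Lipases had a median of 0.11 (-0.20 after median-ratio scaling) and lay below other genes (camera adjusted p = 0.0304, 0.0663 with the block, 0.204 and 0.878 after the 2 scalings, 0.0522 without standard replicate 1, 0.119 without standard replicate 3, and adjusted p = 0.293 with an estimated correlation). Of the 16 lipases 1 was higher by either count, CG5162 (0.40, adjusted p = 0.0274, and 0.711 after median-ratio scaling), with 4 higher and 1 lower under the block. The lipase gene mag was at 485 ± 62.0 and 464 ± 64.4 (0.06, adjusted p = 0.828), and at -0.27 after median-ratio scaling and -0.05 without standard replicate 2. In the sterol and lipid absorption list Npc2f was higher (0.75, adjusted p = 0.0397, and 0.369 after median-ratio scaling), 1 of 14 over all genes (3 higher and 1 lower with the block) and 0 adjusted over the list alone (median 0.30, camera direction down, adjusted p = 0.599). Neither scaling left a call in the other secreted peptidases, other glycosidases, lipases or sterol and lipid absorption.

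Of 6 lysozymes 3 were lower over all genes (5 with the block, 0 after either scaling) and 4 adjusted over the list alone. The list median was -1.27, and -1.60 and -0.85 after the 2 scalings (camera adjusted p = 4.69e-09, and adjusted p = 0.293 with an estimated correlation). LysB, whose copies share reads, was at 1749 ± 439 on glucose and 4662 ± 889 on standard medium (-1.43, adjusted p = 0.0309, and 0.0687 after median-ratio scaling). LysE was at 588 ± 140 and 1433 ± 278 (-1.30, adjusted p = 0.0389, and 0.0881). In the antimicrobial peptides Def fell (-0.84, adjusted p = 0.0301) and Drsl3 rose (0.97, adjusted p = 0.0415), 1 each way of 4 by either count, and neither passed after scaling (median -0.11, camera adjusted p = 0.0807, and 0.0297 without standard replicate 3). Irc rose in the peptidoglycan recognition and Imd regulators (1.06, adjusted p = 0.0104, and 0.0402 after median-ratio scaling), where 1 of 11 was called (4 with the block) and 4 were higher adjusted over the list alone (median 0.25, -0.06 and -0.02 after the 2 scalings, camera down, adjusted p = 0.714). Histone H1 genes such as His1:CG33813, whose values equal those of His1:CG31617, were at 155 ± 19.6 on glucose and 668 ± 392 on standard medium (-1.87, adjusted p = 0.0274, 0.0676 after median-ratio scaling and 0.0855 without standard replicate 3). The gene His1:CG33813 was highest in standard replicates 2 and 3. Of 23 H1 genes 10 were instead highest in standard replicate 1.

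The type II receptor gene put of the TGF-beta/activin pathway was at 7.69 ± 0.585 on glucose and 5.28 ± 0.400 on standard medium (0.47, adjusted p = 0.0182, and 0.361 at 0.18 after median-ratio scaling), 1 of 8 members called by either count (4 with the block). The pathway had a median of 0.36, or 0.11 above the median gene (camera adjusted p = 0.745). The ligand gene daw was at 20.5 ± 6.92 and 14.2 ± 2.33 (0.47, adjusted p = 0.112, 0.0465 with the block, 0.796 after median-ratio scaling, and 0.0465 to 0.796 over the alternatives). babo was at 5.93 ± 0.502 and 4.84 ± 0.803 (0.26, adjusted p = 0.283) and Smox at 7.35 ± 0.664 and 6.20 ± 0.693 (0.21, adjusted p = 0.259). After median-ratio scaling their differences were -0.03 and -0.08, and after quantile normalization -0.01 and -0.05. In the BMP pathway Mad (0.60, adjusted p = 0.0108) and sax (0.37, adjusted p = 0.0209) were higher, 2 of 8 by either count (4 with the block). After median-ratio scaling their adjusted p was 0.0915 and 0.629 (list median 0.26, 0.02 after median-ratio scaling, camera adjusted p = 0.598). Among sugar sensing genes Hnf4 and cbt were higher (0.30 and 0.41, adjusted p = 0.0445 and 0.0492), 2 of 5 by either count, and at -0.01 and 0.09 after median-ratio scaling. The sugar sensing median was 0.30, or -0.01 after median-ratio scaling, with a mean of 0.14 and a camera direction of down (adjusted p = 0.745). sug was at 58.6 ± 13.3 and 74.5 ± 22.0 (-0.32, adjusted p = 0.491) and Thor at 253 ± 50.2 and 166 ± 44.9 (0.63, adjusted p = 0.115, 0.0404 with library weights, and 0.691 at 0.29 after median-ratio scaling). Neither scaling left a call in the TGF-beta/activin pathway, BMP pathway or sugar sensing.

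In metabolism and transport, the amino acid transporter gene CG5535 rose (1.46, adjusted p = 0.0154) and slif fell (-0.55, adjusted p = 0.0288), each also after median-ratio scaling (0.0425 and 0.0369), and slif at 0.206 after quantile normalization. Of 12 amino acid transporters 3 were higher and 1 lower (2 lower with the block, 1 and 1 after median-ratio scaling, 1 and 0 after quantile normalization), and 4 and 2 adjusted over the list alone. Their median was 0.18, -0.15 after median-ratio scaling, with a camera direction of down (adjusted p = 0.0530, 0.0327 with the block, 0.0481 without agar replicate 2, 0.0472 without agar replicate 3 and 0.0428 without glucose replicate 1). The lipase gene bmm fell (-0.73, adjusted p = 0.0195, 0.0205 after median-ratio scaling and 0.0832 after quantile normalization) among starvation and FOXO targets, where 3 of 11 were higher and 1 lower by either count (5 and 2 with the block, 0 and 1 after median-ratio scaling, 0 and 0 after quantile normalization; median 0.28, camera down, adjusted p = 0.474). Genes of autophagy were higher, 6 of 15 over all genes (11 with the block) and 9 adjusted over the list alone, among them Atg8a (0.67, adjusted p = 0.0185) and CG7053 (0.65, adjusted p = 0.0154). After either scaling 0 of the 15 were called. The autophagy median was 0.35, 0.10 above the median gene (camera adjusted p = 0.0453, 0.0663 with the block, 0.120 and 0.0879 after the 2 scalings, and adjusted p = 0.408 with an estimated correlation). It missed the threshold without glucose replicate 3 (0.0934), standard replicate 1 (0.0978) or standard replicate 2 (0.146). Fatty acid oxidation had a median of -0.05 and a mean of 0.03 with 0 of 13 called by limma (3 higher and 2 lower with the block; camera down, adjusted p = 0.00150, 0.672 after quantile normalization, and adjusted p = 0.410 with an estimated correlation). Oxidative phosphorylation had 1 of 23 lower over all genes, Cyt-c-p (-0.40, adjusted p = 0.0460, and 0.978 at -0.02 after quantile normalization), and 0 adjusted over the list alone. Its median was -0.21, and -0.54 and -0.08 after the 2 scalings (camera adjusted p = 5.16e-14, 0.185 after quantile normalization, and adjusted p = 0.345 with an estimated correlation). Sugar transporters had 3 of 13 higher by either count (0 after either scaling), such as Tret1-1 (0.78, adjusted p = 0.0301; median 0.29, adjusted p = 0.521). Lipogenesis and NADPH supply had 2 of 11 higher by either count (3 with the block), SCAP and ATPCL, with 1 other member lower after median-ratio scaling (median 0.12, -0.19 after median-ratio scaling, camera down, adjusted p = 0.349). Glycolysis had 0 of 13 called by limma (1 each way with the block; median 0.27, -0.05 after median-ratio scaling, camera down, adjusted p = 0.449). None of Tret1-1, SCAP and ATPCL passed after scaling.

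Of the progenitor markers and mitogens 4 of 5 were higher over all genes and 5 adjusted over the list alone, including esg, a progenitor cell marker (0.54, adjusted p = 0.0171). After either scaling 0 were called, though the list median of 0.53 stayed above 0 at 0.24 and 0.28 (camera adjusted p = 0.0331, and adjusted p = 0.342 with an estimated correlation). Of the genes for cytosolic ribosomal proteins 14 of 83 were higher over all genes (25 with the block, 0 after either scaling) and 11 adjusted over the list alone, such as RpL5 (0.75, adjusted p = 0.0182). Their median was 0.42, and 0.09 and 0.55 after the 2 scalings (camera adjusted p = 0.598, 0.00602 and 1.15e-13 after the 2 scalings and 0.00414 without standard replicate 1). In standard replicates 2 and 3 these genes lay at -0.50 and -0.53. Ribosome biogenesis had 4 of 18 higher by either count (14 with the block, 0 after either scaling), such as CG8801 (0.90, adjusted p = 0.0176; median 0.39, adjusted p = 0.423, and 0.0491 without glucose replicate 3). Detoxification had 3 of 19 higher and 1 lower (9 and 1 with the block, 0 and 1 after median-ratio scaling, 1 and 1 after quantile normalization), and 6 and 1 adjusted over the list alone (median 0.30, camera down, adjusted p = 0.601). Cyp6a2 rose (1.25, adjusted p = 0.0154, and 0.0612 after median-ratio scaling) and GstD2 fell (-1.70, adjusted p = 0.0171, and 0.0247 after median-ratio scaling). The vacuolar ATPase and copper cell list had 1 of 14 higher by either count (2 with the block), Vha100-1, and a median of 0.02, with -0.31 and 0.21 after the 2 scalings. Its camera direction was down (adjusted p = 0.0436, 0.0501 with the block, 0.155 after quantile normalization, 0.130 without glucose replicate 2, 0.123 without standard replicate 1, 0.249 without standard replicate 3, and adjusted p = 0.594 with an estimated correlation). Enteroendocrine peptides had 3 of 11 higher (6 with the block, 0 after either scaling) and 5 adjusted over the list alone, such as Tk (0.52, adjusted p = 0.0306, and 0.492 after median-ratio scaling; median 0.31, adjusted p = 0.594). The circadian clock had 2 of 8 higher by either count (5 with the block, 0 after either scaling), per and vri (median 0.43, adjusted p = 0.745). The cell division list had 1 of 3 higher by either count, RnrS (0.81, adjusted p = 0.0195; median 0.12, -0.04 and -0.12 after the 2 scalings, camera down, adjusted p = 0.745). Heat shock and Turandot had 1 of 13 higher by either count, Hsp23 (1.14, adjusted p = 0.0176; median 0.54, camera down, adjusted p = 0.745). Mucins and peritrophic matrix had 1 of 5 higher by either count, Muc55B (1.18, adjusted p = 0.0307; median 0.22, -0.11 after median-ratio scaling, camera down, adjusted p = 0.466). Vha100-1, RnrS, Hsp23 and Muc55B, the calls of their lists, passed after neither scaling.

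By fry as deposited, where the shift of most genes favours rises, 9 of 33 lists moved up, 0 down and 21 in either direction. In all, 1715 genes were higher and 72 lower on glucose than on standard medium by limma, 70 of them at least doubled and 26 reduced to 0.5 times or less. The unadjusted p was under 0.05 for 3583 genes, and 4256 did not overlap between groups (53.0%, against 10% by chance). The share of higher calls was 96.0% as deposited, 30.7% after median-ratio scaling (23 higher and 52 lower) and 50% after quantile normalization (28 and 28). With the block 3386 were higher and 290 lower, and with the block and median-ratio scaling 152 and 333. The counts were 2603 and 126 without agar replicate 3 and 1203 and 51 without agar replicate 2. They were 29 and 8 without glucose replicate 1, 4 and 5 without glucose replicate 2, and 67 and 11 without glucose replicate 3. They were 974 and 178 without standard replicate 1, 484 and 25 without standard replicate 2, and 69 and 12 without standard replicate 3. Of the 57 named genes called, CG3290, CG13215, CG15533, Jon25Bii and Jon25Bi kept the call without each library in turn. Calls were lost for 51, 47 and 45 of them without glucose replicates 2, 1 and 3, for 43, 29 and 14 without standard replicates 3, 2 and 1, and for 6 and 1 without agar replicates 2 and 1, with adjusted p of at most 0.137 (Cyt-c-p). After median-ratio scaling 14 of the 57 kept the call and after quantile normalization 12.

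Agar was compared with standard medium to show what the lack of any nutrient does. The most raised genes included enzymes that digest carbohydrate and fat. CG34040 rose from 1.14 ± 0.684 RPKM to 126 ± 102 (5.38, adjusted p = 0.00471) and tobi from 22.4 ± 11.1 to 773 ± 395 (5.01, SE 0.49, adjusted p = 0.00196). Amyrel rose from 0.765 ± 0.0768 to 49.2 ± 24.9 (4.67, SE 0.36, adjusted p = 8.78e-04) and the lipase gene CG8093 from 19.0 ± 5.22 to 303 ± 137 (3.85, adjusted p = 0.00196). The maltase genes Mal-A8, Mal-A7 and Mal-A6 rose by 4.50, 4.47 and 4.43 (adjusted p = 0.00221, 0.00266 and 0.00301), and CG15533 by 4.27 (adjusted p = 8.78e-04). All of these passed under each scaling. Among the largest falls were Jon25Bii, from 1478 ± 269 to 391 ± 143 (-1.97, adjusted p = 0.00626), LysB, from 4662 ± 889 to 1441 ± 705 (-1.80, adjusted p = 0.00925, and 0.0863 after quantile normalization) and Eip71CD, a methionine sulfoxide reductase gene, from 219.9 ± 31.2 to 70.2 ± 42.7 (-1.80, adjusted p = 0.0108, and 0.0818 after quantile normalization).

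Of the amylases and maltases 11 of 13 were higher by either count and 9 after either scaling. Their median was 2.64, or 2.37 above the median gene (camera adjusted p = 7.82e-06, and adjusted p = 0.314 with an estimated correlation). Mal-A1 rose from 94.3 ± 36.8 to 1208 ± 551 (3.60, adjusted p = 0.00292) and Mal-A4 from 9.47 ± 2.43 to 64.2 ± 13.5 (2.64, adjusted p = 0.00173). The 2 not called were Amy-p, at 1075 ± 593 on agar and 733 ± 326 on standard medium (0.42, adjusted p = 0.521, 0.0437 without agar replicate 3, and 0.0437 to 0.967 over the alternatives), and Amy-d. Amy-d was at 759 ± 287 and 437 ± 134 (0.75, adjusted p = 0.0917, 0.0371 with the block, 0.0141 without agar replicate 3, and 0.0141 to 0.259 over the libraries left out in turn). Mal-B1, below the filter, was at 0.644 ± 0.328 and 0.176 ± 0.0587. Of 9 other glycosidases 5 were higher over all genes (7 higher and 1 lower with the block, 2 higher after either scaling) and 6 adjusted over the list alone. Gal was at 56.5 ± 7.21 and 11.7 ± 1.00 (2.17, SE 0.13, adjusted p = 4.56e-04) and Treh rose by 1.50 (adjusted p = 0.00461). The median of the other glycosidases was 0.75 (camera adjusted p = 0.357, and 0.0151 after median-ratio scaling). Of 16 lipases 9 were higher and 2 lower by either count (3 and 2 after median-ratio scaling, 3 and 1 after quantile normalization; median 0.58, camera adjusted p = 0.925). Lip3 was at 2.74 ± 1.39 and 0.0773 ± 0.0522 (1.72, adjusted p = 0.00471), and mag at 490 ± 155 and 464 ± 64.4 (0.04, adjusted p = 0.898, with -0.33 after median-ratio scaling, -0.20 without agar replicate 1 and -0.08 without standard replicate 2).

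**Figure D3:**
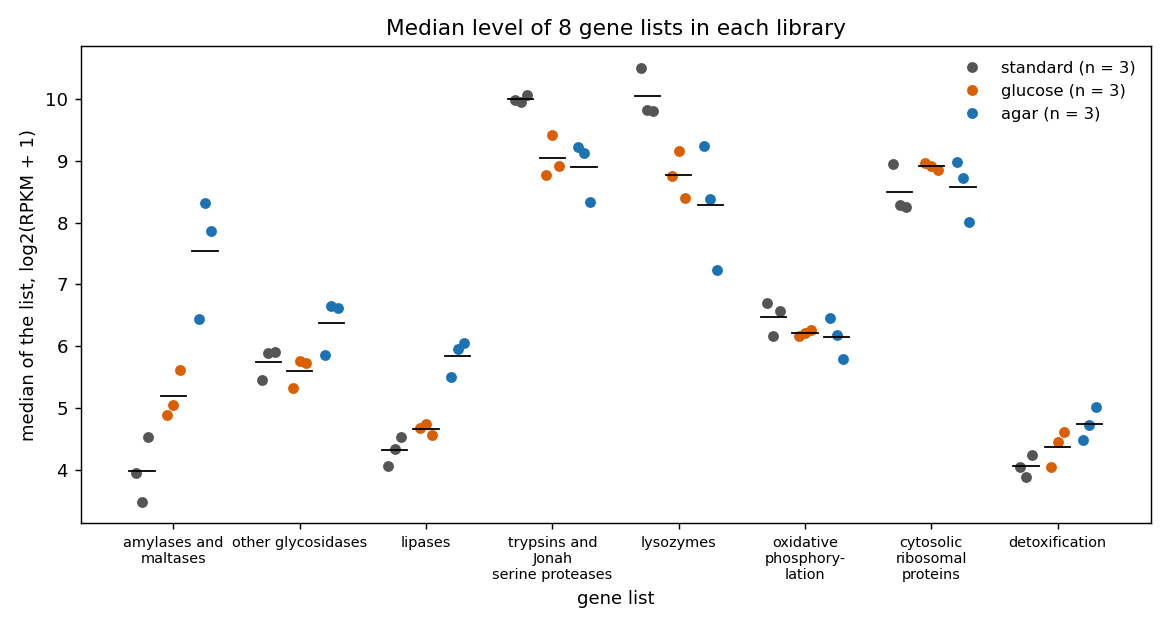
Median log2(RPKM + 1) of the tested members of 8 gene lists (vertical axis) in each library, with 3 points per diet and a black bar at their mean. Medians of the amylases and maltases were 3.49 to 4.53 on standard medium, 4.90 to 5.63 on glucose and 6.44 to 8.32 on agar, whereas the median difference of agar from standard medium for the cytosolic ribosomal proteins was -0.27 after median-ratio scaling and 0.26 after quantile normalization.

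Of 33 trypsins and Jonah serine proteases 13 were lower and 1 higher over all genes (20 and 2 with the block, 14 and 0 after median-ratio scaling, 5 and 0 after quantile normalization), and 17 and 1 adjusted over the list alone. Their median was -0.67, and -1.04 and -0.30 after the 2 scalings (camera adjusted p = 1.65e-21, and adjusted p = 0.146 with an estimated correlation). Jon25Bi fell by 1.76 (adjusted p = 0.00707). Of 22 other secreted peptidases 5 were lower and 1 higher (9 and 2 with the block, 5 and 0 after median-ratio scaling, 2 and 1 after quantile normalization), and 4 and 1 adjusted over the list alone (median -0.07, camera adjusted p = 2.37e-07, 0.123 after quantile normalization, and adjusted p = 0.146 with an estimated correlation). The carboxypeptidase gene CG12374, among the most abundant transcripts, was at 9885 ± 3016 on agar and 17879 ± 1484 on standard medium (-0.89, adjusted p = 0.0147, 0.0588 without agar replicate 2, and 0.00360 to 0.296 over the alternatives). The astacin gene CG15253 fell by 1.36 (adjusted p = 0.0151, and 0.0525 without standard replicate 3). Lysozymes were lower for 5 of 6 by either count (4 after median-ratio scaling, 2 after quantile normalization), with a median of -1.63, or -1.08 after quantile normalization (camera adjusted p = 2.81e-09, and adjusted p = 0.146 with an estimated correlation). LysC, which may share reads with its neighbours, fell by 1.87 (adjusted p = 0.0304, 0.0623 after median-ratio scaling, 0.0798 after quantile normalization and 0.0789 without standard replicate 1). Among antimicrobial peptides Def fell from 4.67 ± 0.171 to 1.05 ± 0.103 (-1.47, adjusted p = 0.00471), 1 of 4 by either count (1 higher with the block). Their median was -0.02 (camera down, adjusted p = 0.0274, 0.0577 with the block, 0.426 and 0.273 after the 2 scalings, 0.110 without agar replicate 1, 0.212 without standard replicate 2, and adjusted p = 0.347 with an estimated correlation). In the sterol and lipid absorption list 5 of 14 were higher by either count (0 after either scaling), such as Npc2e (1.44, adjusted p = 0.00853; median 0.36, camera down, adjusted p = 0.444).

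The sugar transporter genes CG6484 and CG10960 rose by 2.52 and 1.70 (adjusted p = 0.00471 and 0.00384). Over all genes 8 of 13 sugar transporters were higher (3 and 4 after the 2 scalings) and 10 adjusted over the list alone (median 0.42, camera adjusted p = 0.120, and 0.0139 after median-ratio scaling). The amino acid transporter genes slif and CG8785 fell by 1.05 and 1.30 (adjusted p = 0.00381 and 0.00532). Of 12 amino acid transporters 3 were higher and 3 lower by either count (1 and 3 after either scaling). Their median was 0.10, -0.26 and -0.14 after the 2 scalings (camera down, adjusted p = 0.00331, 0.114 and 0.145 after the 2 scalings, and adjusted p = 0.146 with an estimated correlation). sug fell from 74.5 ± 22.0 to 25.9 ± 13.4 (-1.56, adjusted p = 0.0130, and 0.0526 after quantile normalization). Hnf4 was 0.32 higher (adjusted p = 0.0220, -0.01 after median-ratio scaling, and 0.0725 without standard replicate 3). Thus 1 was called each way of the 5 sugar sensing genes by either count (sug alone after median-ratio scaling, 0 after quantile normalization). The sugar sensing median was -0.06 (camera adjusted p = 0.0257, 0.0950 at a median of 0.05 without standard replicate 1, 0.0658 without standard replicate 3, and adjusted p = 0.349 with an estimated correlation). The lipase gene bmm fell by 0.97 (adjusted p = 0.00486) and fbp rose (0.54, adjusted p = 0.0114, and 0.387 after median-ratio scaling) among starvation and FOXO targets, 1 each way of 11 by either count (4 higher with the block, 0 higher and 1 lower after either scaling; median 0.25, -0.10 and -0.02 after the 2 scalings, camera down, adjusted p = 0.204). Thor was at 201 ± 63.3 and 166 ± 44.9 (0.27, adjusted p = 0.452, and -0.10 after median-ratio scaling). The fatty acid synthase gene CG3523 fell by 0.80 (adjusted p = 0.0271, 0.0552 after quantile normalization, and 0.0818 without standard replicate 3) in lipogenesis and NADPH supply, where 2 of 11 were higher and 1 lower over all genes and 1 each way adjusted over the list alone (0 and 2 after median-ratio scaling, 0 and 0 after quantile normalization; median 0.16, -0.17 and -0.04 after the 2 scalings, camera down, adjusted p = 0.120). The medium-chain acyl-CoA dehydrogenase gene CG12262 rose by 1.15 (adjusted p = 0.00748, and 0.0858 after median-ratio scaling) in fatty acid oxidation, where 5 of 13 were higher and 1 lower by either count (5 and 2 with the block, 0 and 2 after median-ratio scaling, 3 and 0 after quantile normalization; median 0.19, -0.16 and -0.06 after the 2 scalings, camera down, adjusted p = 0.393). Autophagy had 9 of 15 higher over all genes and 11 adjusted over the list alone, Atg8a by 0.75 (adjusted p = 0.00605; list median 0.46, 0.15 and 0.17 after the 2 scalings with 0 and 1 called, camera adjusted p = 0.160). Oxidative phosphorylation had 1 of 23 lower by either count, Cyt-c-p (-0.64, adjusted p = 0.00750, and 0.291 after quantile normalization), and a median of -0.31, -0.67 and -0.29 after the 2 scalings (camera adjusted p = 7.06e-13, and adjusted p = 0.347 with an estimated correlation). Glycolysis had 2 of 13 higher over all genes (4 with the block, 0 after either scaling) and 1 adjusted over the list alone (median 0.06, -0.30 and -0.10 after the 2 scalings, camera down, adjusted p = 0.287).

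For the TGF-beta/activin pathway 3 of 8 were higher by either count and 0 after either scaling. put was at 7.30 ± 0.416 on agar and 5.28 ± 0.400 on standard medium (0.40, adjusted p = 0.0112, and 0.633 at 0.09 after median-ratio scaling). The ligand gene myo was at 12.5 ± 4.32 and 7.20 ± 1.20 (0.68, adjusted p = 0.0374, 0.389 after median-ratio scaling, 0.0996 without standard replicate 1). babo was at 7.02 ± 2.0971 and 4.84 ± 0.803 (0.44, adjusted p = 0.0788, 0.0146 with the block, 0.0289 without agar replicate 1, and 0.0146 to 0.736 over the alternatives). daw was at 12.3 ± 0.526 and 14.2 ± 2.33 (-0.17, adjusted p = 0.516) and Smox at 7.35 ± 1.64 and 6.20 ± 0.693 (0.20, adjusted p = 0.277, with -0.12 and -0.10 after the 2 scalings). The median of the TGF-beta/activin pathway was 0.30, -0.02 after median-ratio scaling (camera down, adjusted p = 0.616), and that of the BMP pathway 0.25, -0.09 and -0.04 after the 2 scalings (adjusted p = 0.925). In the BMP pathway 2 of 8 were higher by either count, Mad and sax (3 with the block, 0 after either scaling).

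Of 19 genes of detoxification 12 were higher and 1 lower by either count, against 4 and 5 higher and 1 lower after the 2 scalings. Cyp6g1 rose from 38.5 ± 5.90 to 131 ± 37.0 (1.72, adjusted p = 0.00381; list median 0.62, camera adjusted p = 0.0939, 0.00155 after median-ratio scaling, and 0.0295 without standard replicate 3). Heat shock and Turandot genes had 1 called each way of 13 over all genes (0 higher and 1 lower after either scaling), Hsp23 (0.69, adjusted p = 0.0284, and 0.0940 without agar replicate 2) and Hsp27 (-0.57, adjusted p = 0.0408, and 0.110 without standard replicate 1), and 0 adjusted over the list alone. Their median was 0.14, -0.11 and -0.02 after the 2 scalings (camera down, adjusted p = 0.0161, 0.0905 without agar replicate 3, 0.188 without standard replicate 1, 0.559 after median-ratio scaling, and adjusted p = 0.605 with an estimated correlation). Of the cytosolic ribosomal proteins 11 of 83 were higher over all genes (14 with the block, 0 after either scaling) and 1 adjusted over the list alone, and RpL5 was 0.76 higher (adjusted p = 0.00778). Their median was 0.10, -0.27 and 0.26 after the 2 scalings (camera down, adjusted p = 2.18e-04, up at 0.00554 after quantile normalization, 0.980 at a median of 0.36 without agar replicate 3, 0.360 without standard replicate 1, and adjusted p = 0.702 with an estimated correlation). The ribosome biogenesis list had 2 of 18 higher over all genes (2 and 1 lower with the block) and 1 adjusted over the list alone (median 0.06, -0.26 and -0.23 after the 2 scalings, camera down, adjusted p = 0.0803, 0.0140 without agar replicate 1 and 0.00314 without standard replicate 3). Progenitor markers and mitogens had 3 of 5 higher by either count, such as esg (0.52, adjusted p = 0.00644; list median 0.50, adjusted p = 0.616). Enteroendocrine peptides had 4 of 11 higher (7 with the block) and 5 adjusted over the list alone, such as CCHa2 (0.66, adjusted p = 0.0256, and 0.0653 without agar replicate 2; list median 0.33, adjusted p = 0.616). Peptidoglycan recognition and Imd regulators had 4 of 11 higher by either count, such as Irc (0.84, adjusted p = 0.00532; list median -0.03, camera down, adjusted p = 0.200). Mucins and peritrophic matrix had 2 of 5 higher by either count (3 with the block), Muc68D and Muc55B (list median 0.47, camera down, adjusted p = 0.584). The vacuolar ATPase and copper cell list had 1 of 14 higher by either count, Vha100-1 (3 with the block; median 0.05, -0.32 and 0.16 after the 2 scalings, camera down, adjusted p = 0.0803, 0.0155 after median-ratio scaling, 0.0350 without agar replicate 3 and 0.0119 without standard replicate 2). The circadian clock had 0 of 8 called by limma (3 with the block; median 0.30, -0.02 after median-ratio scaling, camera down, adjusted p = 0.444). Cell division had 1 of 3 higher over all genes, RnrS (0.62, adjusted p = 0.0197, and 0.0669 without agar replicate 2), and 2 adjusted over the list alone (2 with the block; median 0.33, camera down, adjusted p = 0.744). After either scaling 0 members of these last 8 lists were called.

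By fry as deposited, where the shift of most genes favours rises, 11 of 33 lists moved up, 1 down and 22 in either direction. In all, 3031 genes were higher and 179 lower on agar than on standard medium by limma, 181 of them at least doubled and 98 reduced to 0.5 times or less. The unadjusted p was under 0.05 for 4176 genes, and 4025 did not overlap between groups (50.1%, against 10% by chance). The median difference was 0.28 as deposited, -0.01 after median-ratio scaling and 0.03 after quantile normalization. The share of higher calls was 94.4% as deposited, 38.1% after median-ratio scaling (141 higher and 229 lower) and 63.0% after quantile normalization (213 and 125). With the block 4096 were higher and 384 lower, and with the block and median-ratio scaling 439 and 733. The counts were 1574 and 93 without agar replicate 2, 1679 and 109 without standard replicate 3, and 1574 to 3047 higher and 93 to 261 lower over the 9 libraries left out in turn. Of the 70 named genes called 50 kept the call without each library. Calls were lost for 18, 10 and 9 of them without standard replicates 3, 2 and 1, for 17, 8 and 3 without agar replicates 2, 3 and 1, and for 4, 4 and 2 without glucose replicates 1, 2 and 3, with adjusted p of at most 0.142 (Mf). After median-ratio scaling 37 of the 70 kept the call and after quantile normalization 32.

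**Figure D4:**
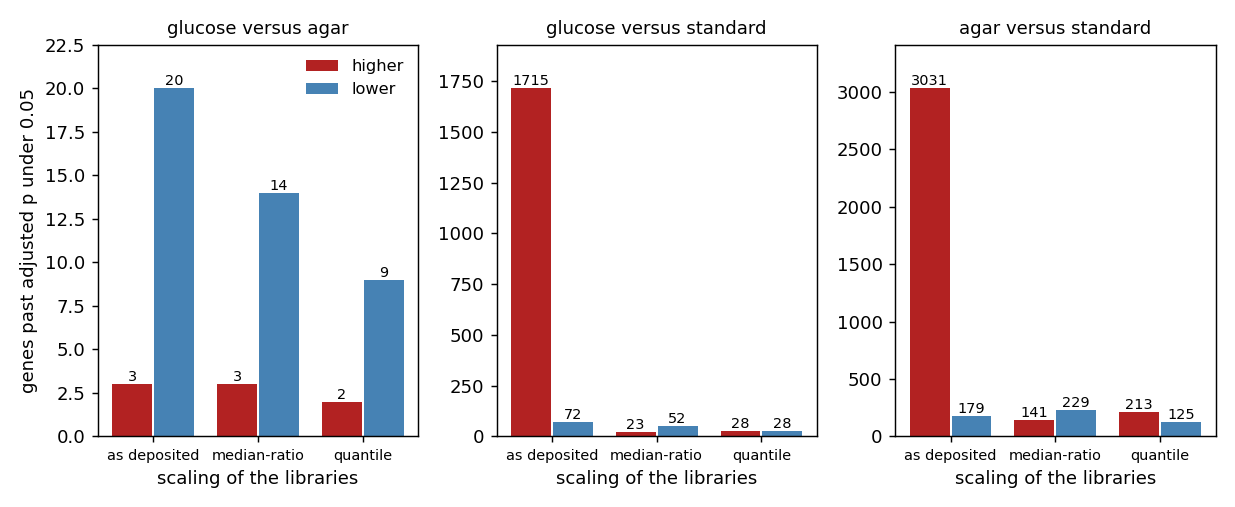
Genes called higher (red bars) and lower (blue bars) in each comparison (vertical axes, number of genes at an adjusted p under 0.05, each panel with its own axis from 0) as deposited, after median-ratio scaling and after quantile normalization (horizontal axes). Against standard medium the calls were 1715 and 72 for glucose and 3031 and 179 for agar as deposited, and 23 and 52, and 141 and 229, after median-ratio scaling.

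As deposited, 1466 genes were called higher and 52 lower on both glucose and agar against standard medium. The product of the 2 sets over all genes, which ignores the shift of most genes, would give 647 and 1.60. Both comparisons use the same standard libraries, so 50 simulations with no change between diets were run and gave 0 and 0. They drew the libraries independently, without the likeness of libraries of the same repeat number. With no change drawn few genes can pass, so the 0 and 0 cannot show how many calls alike the common libraries make. The differences correlated at r = 0.85 across genes, which are not independent replicates, against 0.50 in the simulations, and their covariance was 0.198 against 0.0291. Called alike were 57 genes after median-ratio scaling and 42 after quantile normalization, and as deposited 820 without agar replicate 2. The numbers were 35, 9 and 78 without glucose replicates 1, 2 and 3, and 961, 457 and 80 without standard replicates 1, 2 and 3. Between the comparisons that share the glucose libraries, 2 genes were higher and 1 lower in both, where the product would give 0.640 and 0.179, and r was 0.02 against 0.50 in the simulations. With the block 43 genes were called alike there, 5 without agar replicate 1, 3 without standard replicate 1, 1 without standard replicate 3 and 0 without any 1 of the others.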

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

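The alternatives below were fixed beforehand except those said to be added. A pseudocount of 0.1 moved the genes at least doubled or reduced to 0.5 times in glucose versus standard to 150 and the amylase and maltase median there to 1.28, now past the threshold. A pseudocount of 5 gave 5 genes higher in glucose versus agar, and 42 and 175 at least doubled or reduced to 0.5 times in glucose and agar versus standard. Without a filter 0 were higher, 10 lower and 6 at least doubled or reduced to 0.5 times in glucose versus agar, the amylase and maltase median in glucose versus standard passed at 1.15, and 1 gene was called alike in the comparisons sharing glucose. The filter of 5 RPKM gave 7 higher, 42 lower and 22 at least doubled or reduced to 0.5 times in glucose versus agar, 1058 and 1904 higher in glucose and agar versus standard, 7 lists past the threshold in agar versus standard, and 990 and 5 genes called alike in the comparisons sharing standard and glucose.

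Median-ratio scaling left 23 genes higher and 29 at least doubled or reduced to 0.5 times in glucose versus standard, where the amylase and maltase median passed at 0.94, 141 and 167 in agar versus standard, and 57 and 1 called alike. Quantile normalization gave 9 lower and 7 at least doubled or reduced to 0.5 times in glucose versus agar, 28 higher, 28 lower, 30 at least doubled or reduced to 0.5 times, a median of 1.09 past the threshold and 5 lists in glucose versus standard, 213 higher and 153 at least doubled or reduced to 0.5 times in agar versus standard, and 42 called alike. The cause of the change in direction with scaling was not tested beyond what is given under the weighed patterns. After median-ratio scaling these differences reversed, with or without the block: Hnf4 -0.0088, babo -0.0259, Smox -0.0769, Amy-p -0.171, Amy-d -0.0603 and mag -0.268 in glucose versus standard, and Hnf4 -0.0148, Smox -0.123, mag -0.328 and Thor -0.098 in agar versus standard. After quantile normalization babo was -0.0134 and Smox -0.0459 in glucose versus standard, Smox -0.0982 in agar versus standard and mag -0.0583 in glucose versus agar, where mag was -0.0112 with library weights.

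The fit of 6 libraries gave 0 higher, 2 lower and 1 at least doubled or reduced to 0.5 times in glucose versus agar, 111 lower and a median of 1.27 past the threshold in glucose versus standard, 1871 higher and 119 lower in agar versus standard, and 1 called alike where glucose is shared. The block gave 51 higher, 140 lower and 62 at least doubled or reduced to 0.5 times in glucose versus agar, 3386, 290 and 247 in glucose versus standard, 384 lower in agar versus standard, and 3030 and 43 called alike. It changed no call of a named gene or list other than those printed with the results. Without the variance trend 6 were higher in glucose versus agar. Library weights gave 23 higher, 109 lower and 49 at least doubled or reduced to 0.5 times in glucose versus agar, 3591, 295 and 243 in glucose versus standard with a median of 1.30 past the threshold, 298 lower in agar versus standard, and 2649 and 16 called alike.

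Chosen after seeing the data, the deposited log2 values gave 169 at least doubled or reduced to 0.5 times and a median of 1.28 past the threshold in glucose versus standard. Median-ratio scaling with the block gave 61 higher, 129 lower and 58 at least doubled or reduced to 0.5 times in glucose versus agar, 152 higher, 333 lower and a median of 0.94 past the threshold in glucose versus standard, 439 and 733 in agar versus standard, and 363 and 32 called alike. With standard replicate 1 as the only standard library 0 genes were higher, 2 lower and 1 at least doubled or reduced to 0.5 times in glucose versus agar, 0 were called in the others and 0 alike. This lone library is assumed to vary like the other groups. Glucose versus agar, which does not use it, lost 10 of its 11 named calls there, so the lost calls do not show smaller differences, and the amylase and maltase medians were 1.07 and 2.58 in glucose and agar versus standard. There Amy-p was -0.521, Amy-d -0.204 and mag -0.0341 in glucose versus standard, and Amy-p -0.263 and mag -0.0579 in agar versus standard.

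Camera with an estimated correlation called 0 lists in each comparison, so the amylase and maltase medians of -1.39 (glucose versus agar) and 2.64 (agar versus standard) lost their calls. Fry for direction called 3 lists in glucose versus agar and took the median of 1.27 in glucose versus standard past the threshold, and fry for either direction called 7, 21 and 22.

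Leaving out 1 library at a time gave, from lowest to highest, 0 (agar 2) to 22 (agar 1) higher, 1 (agar 2) to 93 (agar 1) lower and 1 to 67 at least doubled or reduced to 0.5 times in glucose versus agar. In glucose versus standard it gave 4 (glucose 2) to 2603 (agar 3), 5 (glucose 2) to 178 (standard 1) and 9 to 213, with an amylase and maltase median of 0.955 (standard 2) to 1.51 (standard 3). In agar versus standard it gave 1574 (agar 2) to 3047 (agar 1) higher and 93 (agar 2) to 261 (standard 1) lower. Called alike were 9 (glucose 2) to 1880 (agar 3) where standard is shared and 0 (agar 2) to 5 (agar 1) where glucose is. Differences also changed sign. They ran from -0.336 to 0.0187 for babo, glucose versus agar, from -0.0801 to 0.170 for Smox, glucose versus agar, from -0.872 to 0.0768 for Amy-p, glucose versus agar, and from -0.121 to 0.270 for mag, glucose versus agar. They ran from -0.0325 to 0.503 for Amy-p, glucose versus standard, from -0.0548 to 0.161 for mag, glucose versus standard, and from -0.205 to 0.186 for mag, agar versus standard. 1 read per kilobase stood for up to 0.0287 RPKM, which sets the lowest level that the depth can show for a transcript of that length. Genes below the filter of 1 RPKM were tested in the fit without a filter.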

Other observations

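Of the tests below, those of genomic DNA, of dividing cells, of signal recognition particle and RNase RNA, of agar replicate 3 alone and of scaling were chosen only after the result was seen. A set of genes, chosen after their values were seen, was nearly absent from some libraries of every diet. CG16826 was at 134.8, 94.8, 69.1 and 123.5 RPKM in agar replicates 1 and 3, glucose replicate 3 and standard replicate 3 and under 0.45 in the other 5 libraries, and CG1678 and CG34212 were at 22 or more in the same 4 libraries only. No cause was tested.

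Most genes lay higher on glucose and on agar than on standard medium, by a median of 0.25 and 0.28. If a few abundant transcripts took more of the reads on standard medium, the reads left for all other genes should be fewer there. The 100 genes with the most reads held 19.1 ± 1.00% of the reads on glucose, 17.9 ± 2.96% on agar and 24.8 ± 2.36% on standard medium, and the log2 difference of the reads outside them was 0.11 for glucose and 0.13 for agar, or 0.413 and 0.451 of the shift. Genes with equal or nearly equal values, such as histone H1 copies, were each counted in these sums, so shared reads entered repeatedly. The share of His1:CG33843 was 0.00413 to 0.00524 of the reads on standard medium, 0.00188 to 0.00262 on glucose and 0.000842 to 0.0026 on agar. The repeats of these copies thus widened the difference. How much of the shift the explanation covers stays open, and it cannot be told apart here from others. No biological explanation was tested.

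By the median of each class, histone and ribosomal RNA genes were far higher in standard replicates 2 and 3, although 10 of the 23 histone H1 genes were highest in standard replicate 1. Those 10 had equal or nearly equal values and are not separate observations. More RNA without a poly(A) tail could raise them. In those libraries 103 small nuclear and nucleolar RNA genes were at -0.118 and -0.39 (interquartile range 0.69 and 0.885), but 2 signal recognition particle RNA genes with equal values were at 1.73 and 1.09, and 2 genes of RNase P and RNase MRP RNA at 0.90 and -0.05. These classes moved apart, so the explanation stays open. Genomic DNA could raise genes with many copies, but with 100 copies of the histone genes it would have put every single gene at 4.22 and 2.68 RPKM or more, and shares of 0.572 and 0.473 of all genes lay below that. More dividing cells might raise histones. The 17 cell division genes were at 0 and -0.29, but 14 of them were below the filter, so this stays open as well.

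Cytosolic ribosomal protein genes lay 0.334 higher on glucose than on agar. Without agar replicate 3 the median was 0.0686 (adjusted p = 0.00251 by limma's camera), so most of it may rest on that library. Scaling does not account for it, as the median was still 0.278 after quantile normalization. No biological explanation was tested.

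In each comparison the 6 libraries were also split in the 9 other ways, 10 splits in all, too few for a share under 0.05. The real split gave 23, 1787 and 3210 calls and the highest other 0, 0 and 0, also among the 4 splits that part all 3 pairs, so 1, 1 and 1 of the 10 splits, the real one itself, had as many. At an unadjusted p under 0.05 the real split gave 845, 3583 and 4176 genes. The highest others, 1164, 508 and 1493, parted only 1 repeat pair. Others parting all 3 gave at most 98, 250 and 88. For glucose versus agar 1164 exceeded the diets, but that split (agar 1, glucose 1 and 2) kept repeats 1 and 3 whole.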
